A study of Homo sapiens and Mus musculus with 12 samples.

How the data were processed

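Total RNA from 12 libraries was measured by RNA sequencing of SMART-Seq v4 PLUS libraries after column extraction, per the labels. Of these, 6 came from human alveolar bone mesenchymal stem cells in culture, 3 untreated and 3 treated with RXDX-106, a TAM receptor inhibitor according to the design text. The other 6 came from mouse tooth extraction sockets, 3 labelled wild type and 3 labelled Mertk knockout. The processing notes name cutadapt 2.3, FastQC 0.11.8 and STAR, whose version they write as 2.8.8a, and give the mouse build GRCm39 for every sample. The human table carries human Ensembl identifiers, so no genome positions are printed here. The program that assigned reads to genes and its annotation release are not given in the sources used here.

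The authors deposited 1 table per organism, in the unit TPM (transcripts per 1000000), with 1 column per library. Each column summed to 1000000 within rounding, and values were rounded to 2 decimals. TPM keeps no read totals, so the depth of each library is unknown, and no counting interval or detection floor is given. A gene listed at 0 is therefore described as listed at 0, and no fold is given against it. The human table listed 61546 identifiers, of which 20702 had no symbol, and the mouse table listed 55492.

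All comparisons used the deposited TPM with no further scaling. Genes with a mean of at least 1 TPM over the 6 libraries of an organism were tested, 13940 in human and 13262 in mouse. Log2(TPM + 1) was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and an intensity trend, treated against untreated and labelled knockout against labelled wild type. Tests were two-sided, p-values were adjusted by Benjamini and Hochberg over the genes tested, and the threshold was an adjusted p of 0.05. Folds are ratios of mean TPM, and log2 fold changes come from the fit, with its standard error (SE). Replicates were labelled as biological, and nothing else in the labels says whether they came from separate cultures, donors or animals, so the p-values measure only the spread between these libraries. An exact permutation test of 3 libraries against 3 cannot give a p below 0.1, and none is used as a threshold here.

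Gene lists for pathways and cell types were fixed before the data were examined, as were the tests, the rule for named genes and the alternative settings. There were 23 human lists and 32 mouse lists, of which 19 and 31 held at least 3 tested genes and were tested. Lists were tested with limma camera against all other genes, with a preset correlation of 0.01 and adjustment over the lists of the organism. Camera with a correlation estimated from the residuals and fry, which asks whether the genes of a list move on balance in one direction, served as alternatives. The members of each list were also adjusted over the list alone. Human genes that rose or fell were matched to mouse genes by symbol without regard to case and tested as 2 lists in the mouse fit, with adjustment over the 2 directions. No orthology table was used, so symbols stand in for orthology.

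The genes named were the TAM receptors and their ligands, the 10 largest rises and the 10 largest falls among genes past the threshold whose groups did not overlap, ranked by log2 fold change of TPM + 1, which understates the change of scarce genes, and up to 4 members with the smallest p of each list past the threshold and of the osteogenic regulator and bone matrix lists. Predicted mouse genes were passed over, and where fewer than 10 genes passed in a direction, those with the next smallest p were added and are said not to pass. Not every gene the rule picks is printed. Other list members given as examples, and all genes in the closing section outside this rule, were chosen after their values were seen. Y-linked genes and XIST were left out of the human tables.

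The settings varied were a pseudocount of 0.1, no filter on low TPM, a minimum mean of 5 TPM, median-ratio scaling over genes with a mean of at least 10 TPM, quantile normalization, rescaling without mitochondrial, ribosomal protein and haemoglobin genes, limma without the trend, limma array weights, the replicate number as a block, and leaving out each library in turn. Rescaling without structural RNAs (7SL, 7SK, RMRP, RPPH1, 5.8S ribosomal RNA and their pseudogenes) was added after the data had been seen, as was leaving mitochondrially encoded genes out of the match to mouse. The procedure was tested on simulated data with 50 genes changed at each of 4 folds, all drawn from genes above about 10 TPM. Noise was drawn independently for each gene, so the simulation held no shift of whole libraries and no correlation between genes. Its figures do not cover scarcer genes or such shifts. In the human simulation 19, 37, 49 and 50 genes were recovered at folds of 1.5, 2, 4 and 8, and 4 of 13740 unchanged genes were called. In the mouse simulation 18, 37, 50 and 49 were recovered and 7 of 13062 unchanged genes were called. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.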

Results

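The 12 libraries form 4 groups of 3, from cultured human alveolar bone mesenchymal stem cells with and without RXDX-106 and from mouse tooth extraction sockets labelled wild type (C57BL/6j) or Mertk knockout. The design text sets both beside each other to ask how loss of TAM signaling (TYRO3, AXL and MERTK, receptor tyrosine kinases that bind GAS6 and protein S) bears on bone differentiation and healing. Sequencing depth is unknown from TPM. Human libraries had 22731 to 23178 genes above 0, and mouse libraries had 18589 to 19703. Values are mean TPM ± SD over n = 3 libraries per group throughout, and adjusted p-values are from limma.

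The human comparison asks which transcripts differed in mesenchymal stem cells treated with RXDX-106. SPARC, a collagen-binding glycoprotein of bone matrix, rose 1.54-fold, from 3665 ± 376 to 5644 ± 113 TPM. COMP, a cartilage and tendon matrix protein, rose 2.48-fold, from 6.68 ± 1.27 to 16.6 ± 1.46 TPM, and HAPLN1, which links aggrecan to hyaluronan, rose 2.05-fold, from 18.2 ± 2.7 to 37.2 ± 1.91 TPM. ACTA2, smooth muscle actin, rose 1.66-fold, from 189 ± 21.98 to 314 ± 5.17 TPM. Among genes that fell, CRABP2, which carries retinoic acid in the cell, went from 101 ± 5.89 to 65.98 ± 7.53 TPM, and IGFBP2, which binds insulin-like growth factors, went from 56.8 ± 2.26 to 36.5 ± 3.05 TPM. All of these genes passed the threshold, but each lost its call in 5 of the 6 fits that left out 1 library.

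Of the TAM receptors and ligands, AXL and GAS6 were the most abundant and none of the 4 tested genes passed the threshold. AXL (ENSG00000167601) was at 98.2 ± 11.8 TPM untreated and 116 ± 2.78 TPM treated, adjusted p = 0.19. Its log2 fold change of 0.24 became 0.01 with median-ratio scaling, whereas it passed with array weights, adjusted p = 0.010, and without untreated replicate 2, adjusted p = 0.028. GAS6 (ENSG00000183087) was at 222 ± 20.8 and 229 ± 9.89 TPM, adjusted p = 0.78. Its log2 fold change of 0.05 turned negative, to -0.19, with median-ratio scaling. TYRO3 (ENSG00000092445) was at 3.67 ± 0.587 and 3.42 ± 0.775 TPM, adjusted p = 0.78. PROS1 (ENSG00000184500), which encodes protein S, was at 4.96 ± 0.356 and 6.37 ± 0.74 TPM, adjusted p = 0.21. MERTK was between 0.02 and 0.08 TPM in the untreated libraries, was listed at 0 in the treated ones, and was below the filter. Adjusted over the list alone 0 of 4 passed with limma, as at an unadjusted p under 0.05. Camera gave an adjusted p of 0.85 in the downward direction, although the median log2 fold change of 0.14 and the mean of 0.13 were positive.

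Across all 13940 genes, 137 rose and 10 fell, and 30 of these changed at least 2-fold in TPM + 1 by the fit. Among named genes with a protein product, the largest rises in log2(TPM + 1) were those of PTPN12, a protein tyrosine phosphatase (31.5 ± 3.28 to 95.4 ± 26.5 TPM, adjusted p = 0.028), and TM4SF20, a membrane protein (11.2 ± 2.01 to 32.1 ± 1.63 TPM, adjusted p = 0.018). Next on that scale came ATP2C2, a calcium pump of the secretory pathway (0.58 ± 0.299 to 3.22 ± 0.481 TPM, adjusted p = 0.033), whose ratio of means was higher at 5.56, and JAK1, a kinase of cytokine receptors (35.5 ± 11.99 to 91.6 ± 13.7 TPM, adjusted p = 0.03). JAG1, a Notch ligand, rose 2.52-fold (3.64 ± 0.0907 to 9.17 ± 0.0208 TPM, adjusted p = 0.024). NPR3, the clearance receptor of natriuretic peptides, rose 2.38-fold (6.68 ± 0.607 to 15.9 ± 1.99 TPM, adjusted p = 0.028). Log2 fold changes were 1.53 for PTPN12 (SE 0.19), 1.45 for TM4SF20 (SE 0.14), 1.21 for COMP (SE 0.15) and 1.13 for JAG1 (SE 0.13). The other rises of the rule were the noncoding transcripts RN7SL34P (listed at 0 in the untreated libraries, 6.12 ± 2.32 TPM treated, adjusted p = 0.018), SNORA53 and WFDC21P. SNORA53 went from 0.77 ± 1.33 to 6.53 ± 1.301 TPM, adjusted p = 0.046, and WFDC21P from 8.68 ± 1.62 to 24.9 ± 9.66 TPM, adjusted p = 0.041. The calls of SNORA53 and WFDC21P were lost with median-ratio scaling, and pseudogenes and small RNAs that share reads with near-identical copies are uncertain. Over 16 alternative fits, TM4SF20 lost its call in 4, PTPN12 in 6, and JAK1, JAG1 and NPR3 in 8 each.

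TMEM158, a membrane protein, fell 2.39-fold (9.56 ± 1.39 to 3.997 ± 0.822 TPM, adjusted p = 0.03). TNFAIP2, a gene induced by tumor necrosis factor, fell 1.60-fold (82.6 ± 4.34 to 51.7 ± 7.46 TPM, adjusted p = 0.043). CRABP2 and IGFBP2 had adjusted p-values of 0.046 and 0.037. MT-ND4L, a mitochondrially encoded subunit of complex I, fell (1442 ± 251 to 862 ± 20.5 TPM, adjusted p = 0.036). So did RN7SL2, an RNA of the signal recognition particle (185350.0 ± 22132 to 110140.0 ± 7405 TPM, adjusted p = 0.03), and RN7SL128P, a pseudogene of that family (7.003 ± 1.34 to 2.13 ± 0.667 TPM, adjusted p = 0.03). MT-CO2, RN7SKP203 and MTCO2P12 had the next smallest p-values but did not pass, with adjusted p = 0.051, 0.053 and 0.058. Their means went from 2033 to 1409 TPM, 205 to 148 TPM and 8.19 to 3.99 TPM.

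**Figure D1:**
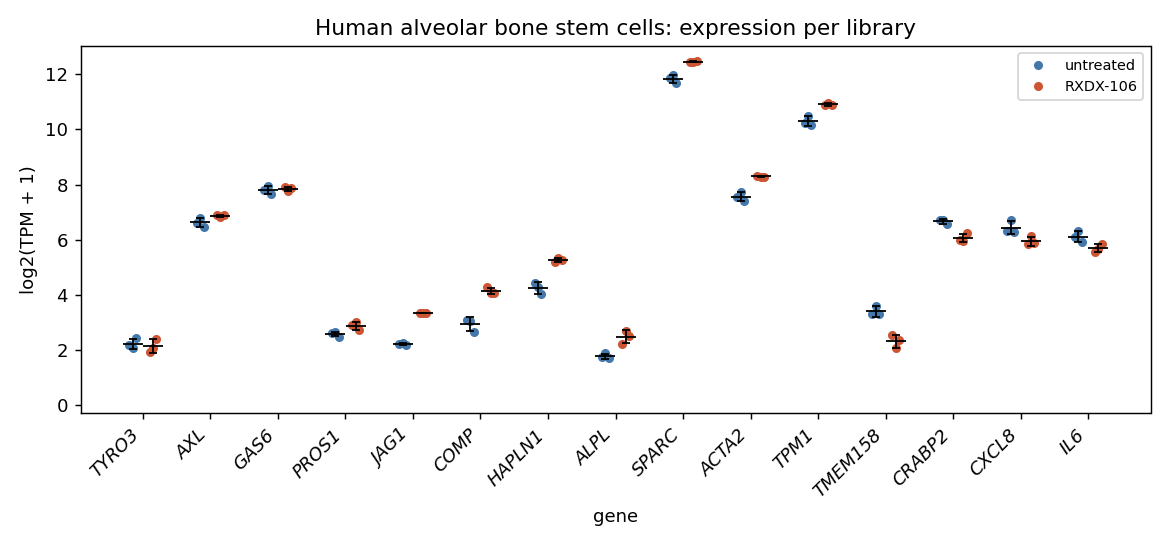
Human genes along the horizontal axis, with log2(TPM + 1) on the vertical axis; points are libraries, blue untreated and red treated with RXDX-106, black lines are group means and bars are ± SD (n = 3). AXL, GAS6, TYRO3 and PROS1 did not pass the test, whereas COMP went from 6.68 to 16.6 TPM and CRABP2 from 101 to 65.98 TPM.

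Of the 19 human lists tested, 9 passed with camera at the preset correlation, and with an estimated correlation none did, the smallest adjusted p being 0.63. With median-ratio scaling and an estimated correlation, a combination added after the data were seen, NF-kappaB and hypoxia passed, both downward, adjusted p = 0.047 each. With fry, which asks whether a list's genes move on balance one way and makes no comparison with other genes, 7 passed, all upward, the BMP response (adjusted p = 0.025) and the interferon response (adjusted p = 0.043) among them. The lists that camera placed below other genes did not pass fry, with adjusted p = 0.17 for NF-kappaB and 0.65 each for hypoxia, ERK output and proliferation. Fry was run only on the deposited scale, where an upward shift of most genes favours upward calls and works against downward ones. The median of all genes had a log2 fold change of 0.21 as deposited and 0.01 with median-ratio scaling. With that scaling list medians were 0.31 for bone matrix, 0.43 for chondrogenic genes, 0.05 for contractile genes, 0.15 each for the ATF4 and cholesterol lists, -0.39 for NF-kappaB, -0.27 for hypoxia, -0.29 for ERK output and -0.14 for proliferation. For the BMP and interferon responses they were 0.18 and 0.14, against 0.36 and 0.33 as deposited.

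Of 6 tested bone matrix and mineralization genes, 1 (SPARC, adjusted p = 0.03) rose and 5 did not pass, while adjusted over the list alone 5 rose. The list's median log2 fold change was 0.54, camera adjusted p = 0.018 (upward), and adjusted p = 0.63 with an estimated correlation. The call was also lost with a minimum mean of 5 TPM, adjusted p = 0.081, and with array weights, adjusted p = 0.073. ALPL, the alkaline phosphatase of mineralizing cells, did not pass over all genes (2.42 ± 0.225 to 4.59 ± 0.872 TPM, adjusted p = 0.071). Neither did ANKH, a pyrophosphate transporter (4.84 ± 1.47 to 9.47 ± 2.53 TPM, adjusted p = 0.078), or SGMS2, a sphingomyelin synthase (39.6 ± 3.01 to 54.4 ± 3.88 TPM, adjusted p = 0.069). With median-ratio scaling, SPARC had a log2 fold change of 0.39 and still passed, adjusted p = 0.011. Its call was lost, however, in 9 of 16 alternative fits, 5 of them with 1 library left out. Of 5 chondrogenic genes, 2 rose, COMP and HAPLN1 (adjusted p = 0.028), and adjusted over the list alone 3 did. That list had a median of 0.64, camera adjusted p = 0.033, and adjusted p = 0.63 with an estimated correlation. ACAN, aggrecan (7.32 ± 0.673 to 12.03 ± 1.58 TPM, adjusted p = 0.06), and SOX9, the chondrogenic transcription factor (4.59 ± 0.8099 to 5.57 ± 0.901 TPM, adjusted p = 0.39), did not pass. After median-ratio scaling COMP kept a log2 fold change of 1.00 and HAPLN1 of 0.78, but each lost its call in 8 of 16 alternative fits. Without untreated replicate 2 the chondrogenic list had an adjusted p of 0.27, without untreated replicate 3 one of 0.078, and without RXDX-106 replicate 3 one of 0.0504. The call was also lost with no filter on low TPM (0.16), with a minimum mean of 5 TPM (0.070), without mitochondrial, ribosomal protein and haemoglobin genes (0.079) and with array weights (0.38).

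Among osteogenic regulators, 0 of 6 passed with limma over all genes and 0 adjusted over the list alone, with 1 at an unadjusted p under 0.05. RUNX2, the main osteoblast transcription factor, was at 17.9 to 20.4 TPM, with a log2 fold change of 0.19 that became -0.03 with median-ratio scaling. MSX1 (39.1 to 48.6 TPM), MSX2 (2.71 to 3.68 TPM) and DLX5 (6.86 to 8.55 TPM), homeobox factors of jaw and tooth development, had adjusted p-values of 0.14, 0.27 and 0.28. The list's median of 0.24 and mean of 0.18 were positive, whereas camera pointed down, adjusted p = 0.89.

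Of 8 contractile genes, 2 rose, ACTA2 (adjusted p = 0.03) and TPM1, a tropomyosin (1267 ± 156 to 1934 ± 66.2 TPM, adjusted p = 0.036), and adjusted over the list alone 4 did. The contractile median was 0.27, camera adjusted p = 0.048, and adjusted p = 0.72 with an estimated correlation. TAGLN, an actin-binding protein of smooth muscle (426 ± 36.5 to 588 ± 8.33 TPM, adjusted p = 0.051), and LMOD1 (6.19 ± 0.4002 to 8.19 ± 0.322 TPM, adjusted p = 0.12) did not pass. With median-ratio scaling TAGLN passed as well, with a log2 fold change of 0.23. The contractile call was lost with that scaling, adjusted p = 0.24, and without untreated replicate 1 (0.061), untreated replicate 3 (0.084) or RXDX-106 replicate 1, 2 or 3 (0.070, 0.096 and 0.12). It was also lost with a minimum mean of 5 TPM (0.14), without the trend (0.15), with array weights (0.086) and with the replicate block (0.060). Without structural RNAs it was 0.077, and without mitochondrial, ribosomal protein and haemoglobin genes 0.056.

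Of 13 genes of the ATF4 and unfolded protein response, 1 rose, ASNS, which makes asparagine (57.7 ± 4.47 to 84.7 ± 4.35 TPM, adjusted p = 0.048), and adjusted over the list alone 9 did. The list's median was 0.38, camera adjusted p = 0.0047, and adjusted p = 0.69 with an estimated correlation. HSPA5, the main chaperone of the endoplasmic reticulum, did not pass over all genes (325 ± 37.1 to 449.9 ± 4.79 TPM, adjusted p = 0.058). The stress response factors XBP1 (365 ± 33.7 to 490.4 ± 25.2 TPM, adjusted p = 0.064) and ATF3 (5.49 ± 1.34 to 9.07 ± 0.812 TPM, adjusted p = 0.073) did not either. ASNS lost its call with median-ratio scaling, adjusted p = 0.056, while HSPA5 rose and PHGDH fell past the threshold, with log2 fold changes of 0.24 and -0.33. Of 16 cholesterol synthesis genes, 1 rose, MSMO1, a sterol oxidase (5.83 ± 0.544 to 10.1 ± 0.2696 TPM, adjusted p = 0.043), and adjusted over the list alone 7 did. That list had a median of 0.36, camera adjusted p = 0.0498, and adjusted p = 0.72 with an estimated correlation. CYP51A1 (21.9 ± 2.85 to 31.9 ± 0.957 TPM, adjusted p = 0.065) and STARD4 (3.003 ± 0.679 to 6.19 ± 2.16 TPM, adjusted p = 0.08) did not pass. The cholesterol call was lost on leaving out any 1 library other than RXDX-106 replicate 2. Adjusted p-values were 0.068, 0.053 and 0.084 without untreated replicates 1, 2 and 3, and 0.081 and 0.12 without RXDX-106 replicates 1 and 3. They were 0.19 with a minimum mean of 5 TPM, 0.054 with quantile normalization, 0.069 without the trend, 0.086 with array weights and 0.058 with the replicate block. Without mitochondrial, ribosomal protein and haemoglobin genes the value was 0.056.

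The NF-kappaB, hypoxia and ERK lists were lower relative to other genes with camera at the preset correlation, and none kept its call with an estimated correlation, adjusted p = 0.63 for each. With median-ratio scaling and an estimated correlation NF-kappaB and hypoxia did, adjusted p = 0.047 each, and ERK output did not, adjusted p = 0.11. Of 12 NF-kappaB inflammatory genes 0 passed with limma, over all genes or adjusted over the list alone, with 4 at an unadjusted p under 0.05. The NF-kappaB median was -0.17, camera adjusted p = 9.1e-08, and adjusted p = 0.63 with an estimated correlation. CXCL8, a neutrophil chemoattractant (86.6 ± 15.6 to 60.98 ± 7.098 TPM, adjusted p = 0.084), and the cytokine IL6 (68.4 ± 9.001 to 50.97 ± 4.91 TPM, adjusted p = 0.093) had the smallest p-values. They were followed by CCL2, a monocyte chemoattractant (37.4 ± 1.13 to 30.5 ± 1.01 TPM, adjusted p = 0.12), and PTGS2, which makes prostaglandins (4.2 ± 0.563 to 2.997 ± 0.276 TPM, adjusted p = 0.18). With median-ratio scaling CXCL8, IL6 and CCL2 passed, with log2 fold changes of -0.72, -0.64 and -0.51. Of 14 hypoxia and glycolysis genes 0 passed with limma, over all genes or adjusted over the list alone, with 1 at an unadjusted p under 0.05. The hypoxia list had a median of -0.05, camera adjusted p = 0.00029, and adjusted p = 0.63 with an estimated correlation. Among its smallest p-values were those of the glycolytic enzymes ALDOA (969 ± 78.8 to 836 ± 10.8 TPM, adjusted p = 0.18) and ENO1 (823 ± 117 to 735 ± 37.6 TPM, adjusted p = 0.39) and the mitophagy gene BNIP3 (184 ± 23.7 to 161 ± 8.94 TPM, adjusted p = 0.31). With median-ratio scaling these 3 passed, with log2 fold changes of -0.44, -0.39 and -0.42, as did SLC2A1 and PGK1, with -0.35 and -0.29. ADM, adrenomedullin, was at 92.4 to 107 TPM, and its log2 fold change of 0.21 became -0.02 with median-ratio scaling. Of 13 genes of ERK pathway output 0 passed with limma, over all genes or adjusted over the list alone, with 1 at an unadjusted p under 0.05. The ERK list had a median of -0.07, camera adjusted p = 0.00039, and adjusted p = 0.63 with an estimated correlation. SPRY4, a feedback inhibitor of the pathway (4.34 ± 0.603 to 3.18 ± 0.238 TPM, adjusted p = 0.2), IER3 (91.1 ± 10.1 to 78.8 ± 2.99 TPM, adjusted p = 0.26) and PHLDA1 (33.9 ± 4.64 to 28.9 ± 1.17 TPM, adjusted p = 0.29) had lower means. With median-ratio scaling CCND1, IER3 and PHLDA1 passed, with log2 fold changes of -0.24, -0.43 and -0.44. EGR1, an immediate early factor, had a higher mean (24.1 ± 2.96 to 29.2 ± 0.738 TPM, adjusted p = 0.18).

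Of 18 proliferation genes 0 passed with limma, over all genes or adjusted over the list alone, with 3 at an unadjusted p under 0.05. The list's median of 0.03 and mean of 0.05 were positive as deposited, whereas camera pointed down relative to other genes, adjusted p = 0.033, and adjusted p = 0.72 with an estimated correlation. The DNA replication helicase genes MCM2 (2.46 ± 0.555 to 4.49 ± 0.756 TPM, adjusted p = 0.081) and MCM5 (2.29 ± 0.262 to 3.5 ± 0.504 TPM, adjusted p = 0.15) had the smallest p-values. MCM6 (5.03 ± 0.897 to 6.73 ± 0.386 TPM, adjusted p = 0.16) and MCM3 (11.2 ± 1.83 to 14.1 ± 1.75 TPM, adjusted p = 0.21) came next. This call was lost with median-ratio scaling, adjusted p = 0.34, and without untreated replicate 1 (0.061), untreated replicate 2 (0.094), RXDX-106 replicate 1 (0.22) or RXDX-106 replicate 3 (0.11). It was also lost with no filter on low TPM (0.093), a minimum mean of 5 TPM (0.42), quantile normalization (0.19), array weights (0.086) and without structural RNAs (0.052).

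The remaining human lists did not pass as deposited. In the TGF-beta response, 1 of 11 rose, CCN2, a matricellular growth factor (387 ± 42.5 to 576 ± 3.01 TPM, adjusted p = 0.037). Adjusted over the list alone 4 did, and camera adjusted p = 0.067, or 0.0071 without untreated replicate 2 and 0.0039 with no filter on low TPM. With median-ratio scaling IGFBP3 also rose and TGFBI fell past the threshold, with log2 fold changes of 0.28 and -0.23. Among collagens and collagen processing, 1 of 25 rose, COL11A1, a fibrillar collagen chain (79.2 ± 8.73 to 143 ± 1.52 TPM, adjusted p = 0.028). Adjusted over the list alone 7 did, and camera adjusted p = 0.30, or 0.011 without untreated replicate 2, 0.029 with no filter and 0.043 with quantile normalization. Its direction turned down with median-ratio scaling, adjusted p = 0.35, where COL11A1, ADAMTS2 and SERPINH1 rose and COL6A1, COL6A2, PLOD1 and PLOD2 fell past the threshold. The 4 falls had log2 fold changes of -0.41, -0.48, -0.33 and -0.20. The BMP response had 0 of 9 past the threshold with limma (1 rose adjusted over the list alone, 5 at an unadjusted p under 0.05) and camera adjusted p = 0.54. The Wnt response had 0 of 5 with limma, also adjusted over the list alone and unadjusted, and adjusted p = 0.21, downward, against a positive median of 0.10 and mean of 0.09. APCDD1 passed with median-ratio scaling, with a log2 fold change of -0.49. In the interferon response 2 of 17 rose, IFIT3 (11.8 ± 1.13 to 22.04 ± 3.05 TPM, adjusted p = 0.033) and IFI6 (61.99 ± 5.25 to 91.97 ± 0.511 TPM, adjusted p = 0.041). Adjusted over the list alone 5 did, and camera adjusted p = 0.17, upward. That list passed with no filter on low TPM (0.023) and with a minimum mean of 5 TPM (0.013). With median-ratio scaling IFIT2 rose past the threshold as well. Of 12 p53 targets 0 passed with limma over all genes and 0 adjusted over the list alone, with 4 at an unadjusted p under 0.05, camera adjusted p = 0.25, or 0.024 with no filter. Stromal cell markers had 0 of 12 past the threshold with limma (2 rose adjusted over the list alone, 7 at an unadjusted p under 0.05). Their camera adjusted p was 0.85, downward, against a positive median of 0.18 and mean of 0.14. With median-ratio scaling CD44, NES, PDGFRA and NT5E fell past the threshold, with log2 fold changes of -0.38, -0.53, -0.30 and -0.24. Of 10 matrix proteases and inhibitors 1 rose, ADAMTS1 (24.2 ± 3.04 to 37.8 ± 1.595 TPM, adjusted p = 0.048). Adjusted over the list alone 6 rose and 2 fell, and camera adjusted p = 0.85, downward, against a positive median of 0.25 and mean of 0.13. With median-ratio scaling TIMP1, MMP3 and MMP1 fell past the threshold, with log2 fold changes of -0.23, -0.77 and -0.70. Markers of other cell types were scarce. The filter was reached by 0 of 10 endothelial genes and by 2 of 13 leukocyte and macrophage genes, CD68 and CD14, neither past the threshold. It was also reached by 1 of 10 adipogenic genes, CD36, not past the threshold, and by 1 of 12 epithelial genes. The epithelial gene was DSP, the desmosome protein desmoplakin, which rose (19.7 ± 2.15 to 36.5 ± 0.588 TPM, adjusted p = 0.028), and none of these lists could be tested.

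**Figure D2:**
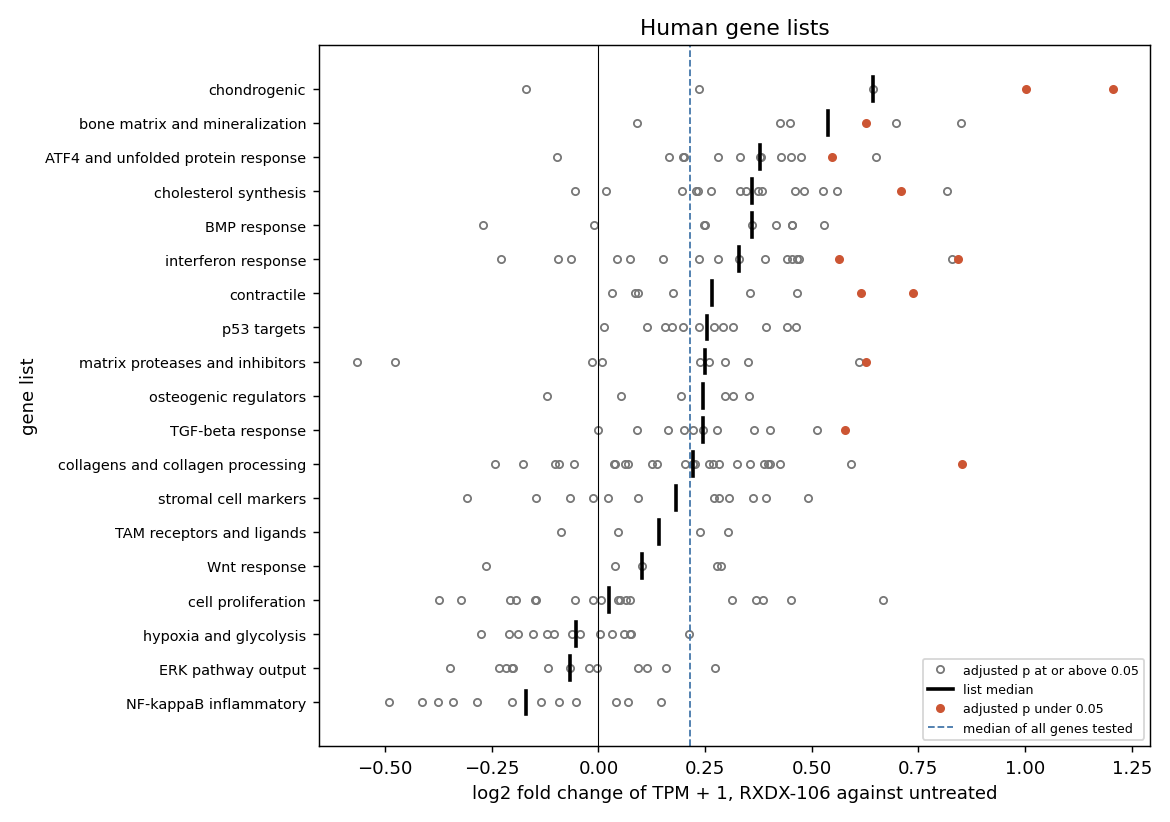
Log2 fold changes of treated over untreated cells (horizontal axis) for the members of human gene lists (vertical axis); filled orange points passed an adjusted p of 0.05, open grey points did not, black bars are list medians and the dashed blue line is the median of all genes, 0.21. Bone matrix and chondrogenic genes centre at 0.54 and 0.64, and NF-kappaB genes at -0.17.

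At an unadjusted p under 0.05 there were 3753 human genes, and groups did not overlap in 4654 (33.4%, against 10% by chance). Structural RNA took 41.9% ± 5.66 of TPM in untreated and 35.1% ± 1.14 in treated libraries. Untreated replicate 2, at 35.5%, lay within the treated range of 33.8% to 36.1%, apart from untreated replicates 1 and 3 at 44.04% and 46.2%. With median-ratio scaling 156 genes rose and 231 fell, with 109 of the 137 rises and 10 of the 10 falls kept. The count rests on single libraries: it was 5, 3096 and 4 without untreated replicates 1, 2 and 3, and 2, 9 and 12 without RXDX-106 replicates 1, 2 and 3. Of the 23 named genes past the threshold, 21, 0, 21, 23, 20 and 20 lost their call in the same order, and limma without the trend or without the filter on low TPM called 0 genes, with 3583 and 4390 at an unadjusted p under 0.05.

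The mouse comparison asks which transcripts differed in extraction sockets between libraries labelled wild type and labelled Mertk knockout. Of 15 inflammatory cytokine genes 14 rose in the libraries labelled knockout and 1 fell, adjusted p = 0.032 with an estimated correlation, and Cxcl2, a neutrophil chemoattractant, rose 13.7-fold, from 593 ± 14.3 to 8126 ± 24.03 TPM. Spp1, osteopontin, rose 2.60-fold, from 506 ± 23.4 to 1315 ± 27.9 TPM, while Bglap, osteocalcin, fell 2.62-fold, from 2519 ± 105 to 963 ± 63.3 TPM. Of 22 proliferation genes 18 fell and 4 did not pass, adjusted p = 0.076 with an estimated correlation or 0.029 with median-ratio scaling added, and Rrm2, a subunit of ribonucleotide reductase, went from 291 ± 3.86 to 124 ± 2.32 TPM. All 10 tested skeletal muscle markers rose. Of 7 salivary gland markers 5 fell, 1 rose and 1 did not pass, and both of these lists had an adjusted p of 0.094 with an estimated correlation.

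Mertk itself went against the labels. It was at 0.71, 0.41 and 0.17 TPM in the libraries labelled wild type and at 8.57, 5.95 and 9.53 TPM in those labelled knockout, a log2 fold change of 2.65 (95% interval 2.04 to 3.26, adjusted p = 3.0e-05). Tyro3 rose with it (0.193 ± 0.168 to 2.15 ± 1.103 TPM, adjusted p = 0.012), and Pros1 fell (11.1 ± 1.43 to 7.47 ± 1.33 TPM, adjusted p = 0.0496), a call lost with median-ratio scaling, adjusted p = 0.11. Axl (5.52 ± 0.873 to 7.77 ± 1.96 TPM, adjusted p = 0.19) and Gas6 (1.7 ± 0.477 to 2.91 ± 0.213 TPM, adjusted p = 0.12) did not pass. Over all genes and adjusted over the list alone, 2 of the 5 rose and 1 fell, with a camera adjusted p of 0.19. Identifiers were ENSMUSG00000014361 for Mertk and ENSMUSG00000027298 for Tyro3. The Y-linked genes Ddx3y and Eif2s3y were listed at 0 in the 3 libraries labelled wild type and were at 5.803 ± 1.95 and 16.3 ± 2.77 TPM in those labelled knockout, adjusted p = 5.6e-05 and 2.4e-07. Xist, which is expressed from the inactive X chromosome, was at 1.49 ± 1.099 and 1.32 ± 0.186 TPM, adjusted p = 0.98. The Y-linked genes Uty and Kdm5d, below the filter, were also listed at 0 in the libraries labelled wild type. In the 3 labelled knockout Uty was at 3.51, 0.91 and 0.38 TPM and Kdm5d at 0, 1.63 and 0.02 TPM. With 2 of 3 sex-linked genes risen, over all genes and adjusted over the list alone, the list had a camera adjusted p of 0.047, or adjusted p = 0.19 with an estimated correlation. That call was lost with median-ratio scaling, adjusted p = 0.072, and without wild-type replicate 2 (0.076) or knockout replicates 1 (0.057) or 3 (0.055). It was also lost with a pseudocount of 0.1 (0.051) and with the replicate block (0.055).

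Of 13 tested genes that neighbour Mertk on its chromosome, 4 rose and 1 fell, over all genes and adjusted over the list alone, with a camera adjusted p of 0.10, or 0.038 with a minimum mean of 5 TPM. The interleukin genes Il1b (1383 ± 36.9 to 13711 ± 336 TPM) and Il1a (16.2 ± 2.19 to 495 ± 22.1 TPM) were among those that rose. Bcl2l11, which promotes apoptosis, also rose (3.76 ± 1.302 to 27.5 ± 1.24 TPM), and the mitotic gene Ckap2l fell (44.5 ± 2.51 to 24.96 ± 3.48 TPM).

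Across all 13262 genes, 2325 rose and 2480 fell, and 1510 of these changed at least 2-fold in TPM + 1 by the fit. The largest rises in log2(TPM + 1) were those of Bpifa1, a secreted protein of airway epithelium (0.4 ± 0.184 to 1672 ± 13.2 TPM, adjusted p = 3.9e-13), and Reg3g, an antibacterial lectin (14.03 ± 2.76 to 4916 ± 190.5 TPM, adjusted p = 2.4e-12). Raet1d, a ligand of the receptor NKG2D (2.1 ± 0.336 to 253 ± 7.77 TPM, adjusted p = 3.6e-11), and Bpifb1, a relative of Bpifa1 (0.213 ± 0.138 to 75.7 ± 4.16 TPM, adjusted p = 8.4e-10), also rose. Cxcl1, a neutrophil chemoattractant, rose 65.1-fold (6.097 ± 1.12 to 397 ± 8.71 TPM, adjusted p = 5.5e-11). Bpifa1 had a log2 fold change of 10.23 (SE 0.11) and Reg3g of 8.37 (SE 0.11). The other 5 were copies of other genes, Rpl15-ps6 (0.0933 to 84.7 TPM), Atp6v0c-ps2 (3.55 to 337 TPM), Rnps1-ps (0.733 to 64.2 TPM), Capza1-ps1 (4.35 to 166 TPM) and Eno1b (11.2 to 377 TPM). Their parents fell, Rpl15 (314 to 259 TPM), Atp6v0c (652 to 474 TPM), Rnps1 (107 to 45.1 TPM), Capza1 (371 to 112 TPM) and Eno1 (1211 to 501 TPM). A copy and its parent may share reads, so the opposite changes of these pairs are uncertain.

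The largest fall in log2(TPM + 1) was that of Mup5, a major urinary protein that carries odorants (273 ± 11.3 to 1.93 ± 0.899 TPM, adjusted p = 6.5e-10). The salivary secretory genes Dcpp3 (from 54.6 ± 4.22 TPM to listed at 0), Dcpp1 (39.7 ± 3.85 to 0.237 ± 0.4099 TPM) and Dcpp2 (46.3 ± 5.86 to 0.63 ± 0.348 TPM) fell. So did Trim12a, of a family of antiviral factors (41.7 ± 8.13 to 0.00667 ± 0.0115 TPM), and Stfa1, a cysteine protease inhibitor (49.4 ± 1.62 to 1 ± 0.7602 TPM). The antibody variable genes Igkv4-55 (176 ± 17.1 to 6.41 ± 3.79 TPM), Igkv6-13 (133 ± 7.83 to 4.6 ± 3.06 TPM) and Ighv1-20 (35.7 ± 8.84 to 0.593 ± 1.03 TPM) fell as well. Dcpp, Mup, pseudogene and antibody variable genes share reads with near-identical copies, so their single values are uncertain.

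**Figure D3:**
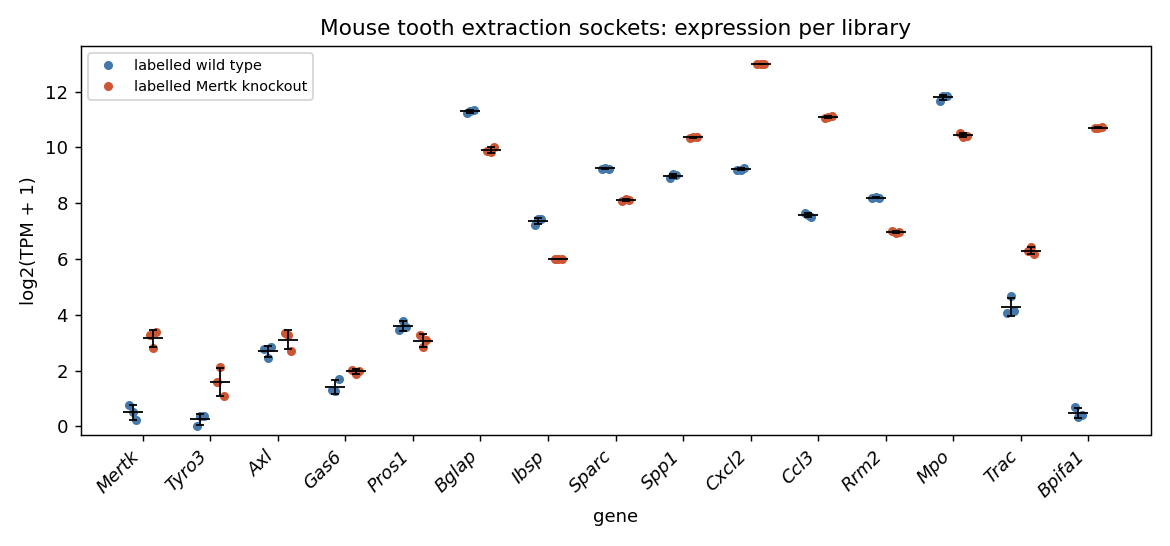
Mouse genes along the horizontal axis, with log2(TPM + 1) on the vertical axis; points are libraries, blue labelled wild type and red labelled Mertk knockout, black lines are group means and bars are ± SD (n = 3). Mertk went from 0.43 to 8.02 TPM, higher in the libraries labelled knockout, Spp1 from 506 to 1315 TPM and Bglap from 2519 to 963 TPM.

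Of 31 mouse lists tested, 12 passed with camera, and 1 of these, inflammatory cytokines, passed with an estimated correlation. With median-ratio scaling and an estimated correlation, cell proliferation passed beside it, adjusted p = 0.029 for both. As deposited, the estimated correlation lay above the preset 0.01 for proliferation (0.03), hypoxia (0.08), muscle (0.06) and periodontal ligament (0.05) genes. It was negative for the TGF-beta (-0.13), neutrophil (-0.07), T and NK cell (-0.02), mast cell (-0.14), basal epithelial (-0.14), salivary (-0.05) and sex-linked (-0.04) lists. For these lists a correlation above the preset one cannot be why the call was lost. Of 15 inflammatory cytokine genes 14 rose and 1 fell, over all genes and adjusted over the list alone. The median log2 fold change was 2.95, camera adjusted p = 4.9e-16, and adjusted p = 0.032 with an estimated correlation. Cxcl3 rose 27.7-fold (56.1 ± 1.32 to 1553 ± 22.7 TPM), Ccl3, macrophage inflammatory protein 1 alpha, rose 11.5-fold (191 ± 11.1 to 2188 ± 40.1 TPM), and Ccl4 rose 7.63-fold (192 ± 9.84 to 1464 ± 48.1 TPM). The monocyte chemoattractant Ccl2 fell (75.5 ± 2.32 to 39.1 ± 4.39 TPM).

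Of 12 bone matrix and mineralization genes, 3 rose and 6 fell, and adjusted over the list alone 3 rose and 7 fell. The list's median was -0.84 and its camera adjusted p 0.19. Beside Bglap (adjusted p = 5.9e-09), Ibsp, bone sialoprotein (164 ± 13.96 to 62.6 ± 0.233 TPM), Sparc (607 ± 7.75 to 275 ± 7.66 TPM) and Alpl (22.7 ± 0.248 to 9.55 ± 2.11 TPM) fell. Spp1 (adjusted p = 2.5e-09), Sgms2 and Enpp1 rose, and Spp1 is also made by macrophages. Of 3 osteogenic regulators, 2 rose, Runx2, the main osteoblast transcription factor (2.89 ± 0.368 to 6.54 ± 2.29 TPM, adjusted p = 0.017), and Atf4 (94.2 ± 2.58 to 109.7 ± 5.05 TPM, adjusted p = 0.035). Sp7, a factor downstream of Runx2, did not pass over all genes (2.25 ± 0.525 to 0.797 ± 0.741 TPM, adjusted p = 0.059). Adjusted over the list alone 2 rose and Sp7 fell, and camera adjusted p = 0.53. Among collagens and collagen processing, 3 of 19 rose and 5 fell, adjusted over the list alone 3 and 6, with camera adjusted p = 0.24. Col1a1 (235 ± 21.3 to 110.4 ± 10.1 TPM) and Col1a2 (229.8 ± 7.82 to 119.7 ± 8.67 TPM), the chains of bone collagen, and the collagen chaperone Serpinh1 (60.4 ± 10.5 to 17.4 ± 1.15 TPM) fell. Col3a1, a collagen of soft tissue, rose (16.99 ± 3.27 to 48.3 ± 3.47 TPM).

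All 5 tested periodontal ligament and tendon genes rose, over all genes and adjusted over the list alone. Their median was 1.25, camera adjusted p = 0.011, and adjusted p = 0.16 with an estimated correlation. They included Postn, periostin (3.86 ± 0.471 to 10.8 ± 3.01 TPM), Thbs4 (1.19 ± 0.741 to 6.997 ± 1.41 TPM), Fmod, fibromodulin (4.17 ± 0.666 to 9.93 ± 0.803 TPM), and Aspn, asporin (0.77 ± 0.711 to 3.15 ± 0.425 TPM), all matrix proteins. In the TGF-beta response 6 of 8 rose, adjusted over the list alone 7. Their mean was 1.03, camera adjusted p = 0.00047, and adjusted p = 0.094 with an estimated correlation. Skil (9.203 ± 0.2003 to 40.5 ± 2.16 TPM) and Smad7 (2.03 ± 0.8504 to 7.16 ± 0.217 TPM), feedback inhibitors of the pathway, Junb (947 ± 57.9 to 1644 ± 196 TPM) and Tgfbi, a matrix protein (130.2 ± 2.905 to 206 ± 5.05 TPM), were among them. Of 15 hypoxia and glycolysis genes, 9 rose and 1 fell, over all genes and adjusted over the list alone. The hypoxia median was 0.57, camera adjusted p = 0.0024, and adjusted p = 0.18 with an estimated correlation. Slc2a1, a glucose transporter (16.9 ± 1.27 to 120.1 ± 2.56 TPM), Pfkfb3, a regulator of glycolysis (9.65 ± 2.53 to 60.03 ± 5.11 TPM), and Bnip3 (44.7 ± 2.005 to 124 ± 15.3 TPM) rose, and Eno1 fell.

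Of 22 proliferation genes, 18 fell and 0 rose with limma, and adjusted over the list alone 19 fell. The proliferation median was -0.69, camera adjusted p = 1.5e-09, and adjusted p = 0.076 with an estimated correlation, or 0.029 when median-ratio scaling was added, under which 16 fell. Mcm6, of the replication helicase (172 ± 5.01 to 90.5 ± 4.74 TPM), Tyms, thymidylate synthase (131 ± 6.92 to 68.4 ± 4.34 TPM), and Ccnb2, cyclin B2 (181 ± 7.06 to 103 ± 5.93 TPM), fell with Rrm2 (adjusted p = 3.2e-08).

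Of 13 neutrophil markers, 8 fell and 2 rose, adjusted over the list alone 8 and 3. The neutrophil median was -0.39, camera adjusted p = 0.0034, and adjusted p = 0.12 with an estimated correlation. The granule genes Ngp (31887 ± 784 to 16986 ± 323 TPM), Ltf, lactoferrin (6827 ± 110.0 to 3770.2 ± 43.5 TPM), and Mpo, myeloperoxidase (3563 ± 239.8 to 1398 ± 67.7 TPM), which are made by maturing neutrophils in marrow, fell. Csf3r, the G-CSF receptor (221 ± 11.8 to 598 ± 5.504 TPM), and the chemokine receptor Cxcr2 (78.6 ± 6.39 to 219.9 ± 8.34 TPM) rose. S100a8 and S100a9 together held 10.3% ± 0.464 and 10.8% ± 0.454 of TPM. Of 10 T cell and NK cell markers, 8 rose and 1 fell, over all genes and adjusted over the list alone. The list had a median of 1.07, camera adjusted p = 0.0068, and adjusted p = 0.14 with an estimated correlation. The T cell receptor genes Trac (18.9 ± 4.73 to 77.7 ± 6.78 TPM), Cd3g (16.1 ± 1.13 to 46.1 ± 2.73 TPM) and Cd3e (10.1 ± 1.68 to 26.8 ± 2.09 TPM) rose, whereas Nkg7, of cytotoxic granules, fell (439 ± 19.2 to 237 ± 17.3 TPM). Of 7 mast cell markers, 6 fell and 1 rose, over all genes and adjusted over the list alone. Its median was -1.63, camera adjusted p = 0.020, and adjusted p = 0.16 with an estimated correlation. The mast cell proteases Cpa3 (72.3 ± 1.68 to 22.8 ± 2.93 TPM), Tpsb2 (13.3 ± 1.796 to 1.38 ± 1.26 TPM) and Cma1 (17.5 ± 3.904 to 4.03 ± 1.55 TPM) fell, and Hdc, which makes histamine, rose (294 ± 15.3 to 1058 ± 24.4 TPM). The mast cell call was lost with a minimum mean of 5 TPM, adjusted p = 0.13.

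Macrophage markers did not pass as a list, camera adjusted p = 0.10, or 0.042 with quantile normalization, but 5 of 13 rose and 1 fell, over all genes and adjusted over the list alone. Cd14, a co-receptor for bacterial lipopolysaccharide (461 ± 25.4 to 2695 ± 144 TPM), and Csf1r, the M-CSF receptor (75.7 ± 1.18 to 94.8 ± 3.43 TPM), rose. Aif1 fell (32.8 ± 4.104 to 24.1 ± 2.26 TPM), a call lost with median-ratio scaling. Of 9 alternative macrophage genes, 2 rose and 4 fell, adjusted over the list alone 3 and 4. Arg1, arginase, rose (39.3 ± 1.68 to 385 ± 1.25 TPM), and Chil3, a chitinase-like protein, fell (6446 ± 123 to 3836 ± 43.9 TPM). Its median of -0.12, mean of 0.24 and downward camera test (adjusted p = 0.53) differed in sign. Of 10 efferocytosis genes, 2 rose and 1 fell, over all genes and adjusted over the list alone, with camera adjusted p = 0.22. Abca1, which exports cholesterol (0.61 ± 0.5197 to 6.43 ± 1.13 TPM), rose. Mfge8, which bridges apoptotic cells to phagocytes (24.4 ± 1.13 to 15.03 ± 1.81 TPM), fell. Of 11 osteoclast genes, 2 rose and 2 fell, over all genes and adjusted over the list alone, with camera adjusted p = 0.74. Acp5, the osteoclast acid phosphatase (79.4 ± 4.61 to 139.8 ± 4.01 TPM), rose, and Mmp9 fell (843 ± 12.4 to 727 ± 7.85 TPM).

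All 10 tested skeletal muscle markers rose, over all genes and adjusted over the list alone. The muscle median was 1.16, camera adjusted p = 2.4e-07, and adjusted p = 0.094 with an estimated correlation. The contractile genes Myl1 (54.4 ± 3.57 to 159.9 ± 3.48 TPM), Tnnc2 (52.3 ± 2.58 to 137 ± 16.6 TPM), Tnnt3 (50.7 ± 1.23 to 111 ± 5.26 TPM) and Mylpf (52.4 ± 3.39 to 103 ± 1.43 TPM) had the smallest p-values. Of 7 salivary gland markers, 5 fell and 1 rose, over all genes and adjusted over the list alone. The salivary median was -3.95, camera adjusted p = 0.00047, and adjusted p = 0.094 with an estimated correlation. Bpifa2, a salivary secretory protein, went from 14.7 ± 2.8 TPM to listed at 0. Car6, a secreted carbonic anhydrase, fell (5.06 ± 1.01 to 0.46 ± 0.616 TPM), while the water channel gene Aqp5 rose (16.03 ± 0.554 to 22.2 ± 1.82 TPM). Of 6 basal epithelial markers, 3 rose, over all genes and adjusted over the list alone. The epithelial median was 1.01, camera adjusted p = 0.021, and adjusted p = 0.16 with an estimated correlation. They were Krt15, a keratin (4.16 ± 0.6298 to 38.98 ± 7.93 TPM), Epcam, an adhesion protein (9.39 ± 2.38 to 25.6 ± 2.08 TPM), and Sfn (1.95 ± 0.801 to 5.3 ± 0.0889 TPM), while Krt14 did not pass (0.65 ± 0.646 to 2.02 ± 0.979 TPM, adjusted p = 0.083).

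The other mouse lists did not pass. In the chondrogenic list 2 of 6 rose, among them Chad, chondroadherin (1.13 to 29.6 TPM), camera adjusted p = 0.13. In the BMP response 3 of 4 rose, Id1 among them (31.6 to 52.9 TPM), adjusted p = 0.19. Of 5 Wnt response genes 1 rose, Tcf7 (6.25 to 22.7 TPM), adjusted p = 0.17. Of 4 endothelial markers 1 rose, Pecam1 (15.8 to 21.95 TPM), adjusted p = 0.26. Counts for these 4 lists were equal when adjusted over the list alone. In the adipogenic list 1 of 6 fell, Cebpa, and 0 passed adjusted over the list alone, with camera adjusted p = 0.90, downward, against a median and mean of 0.02. The call of Cebpa was lost with median-ratio scaling. In the interferon response 4 of 17 rose and 5 fell, over all genes and adjusted over the list alone, camera adjusted p = 0.53. Cxcl10 (8.57 to 75.1 TPM) and Isg15 (29.9 to 150.1 TPM) rose. Oasl2 (37.04 to 5.85 TPM) and Xaf1 (19.2 to 1.91 TPM) fell. Of 8 B cell and plasma cell markers 3 rose and 3 fell, over all genes and adjusted over the list alone, camera adjusted p = 0.96. With median-ratio scaling 5 rose and 3 fell. The B cell gene Ms4a1 rose (30.02 to 84.7 TPM), and the antibody chain gene Ighm fell (1132 to 756 TPM). Erythroid markers had 2 of 9 rise and 4 fall, adjusted over the list alone 2 and 5, camera adjusted p = 0.26. With median-ratio scaling 2 of them rose and 2 fell. Keratinized epithelial markers had 1 of 5 rise and 2 fall, camera adjusted p = 0.53. Schwann cell markers had 1 of 4 rise and 2 fall, camera adjusted p = 0.44. Both counts were equal when adjusted over the list alone. Of the tooth-forming cell markers only Odam, of junctional epithelium, reached the filter, and it rose (12.3 to 42.4 TPM).

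**Figure D4:**
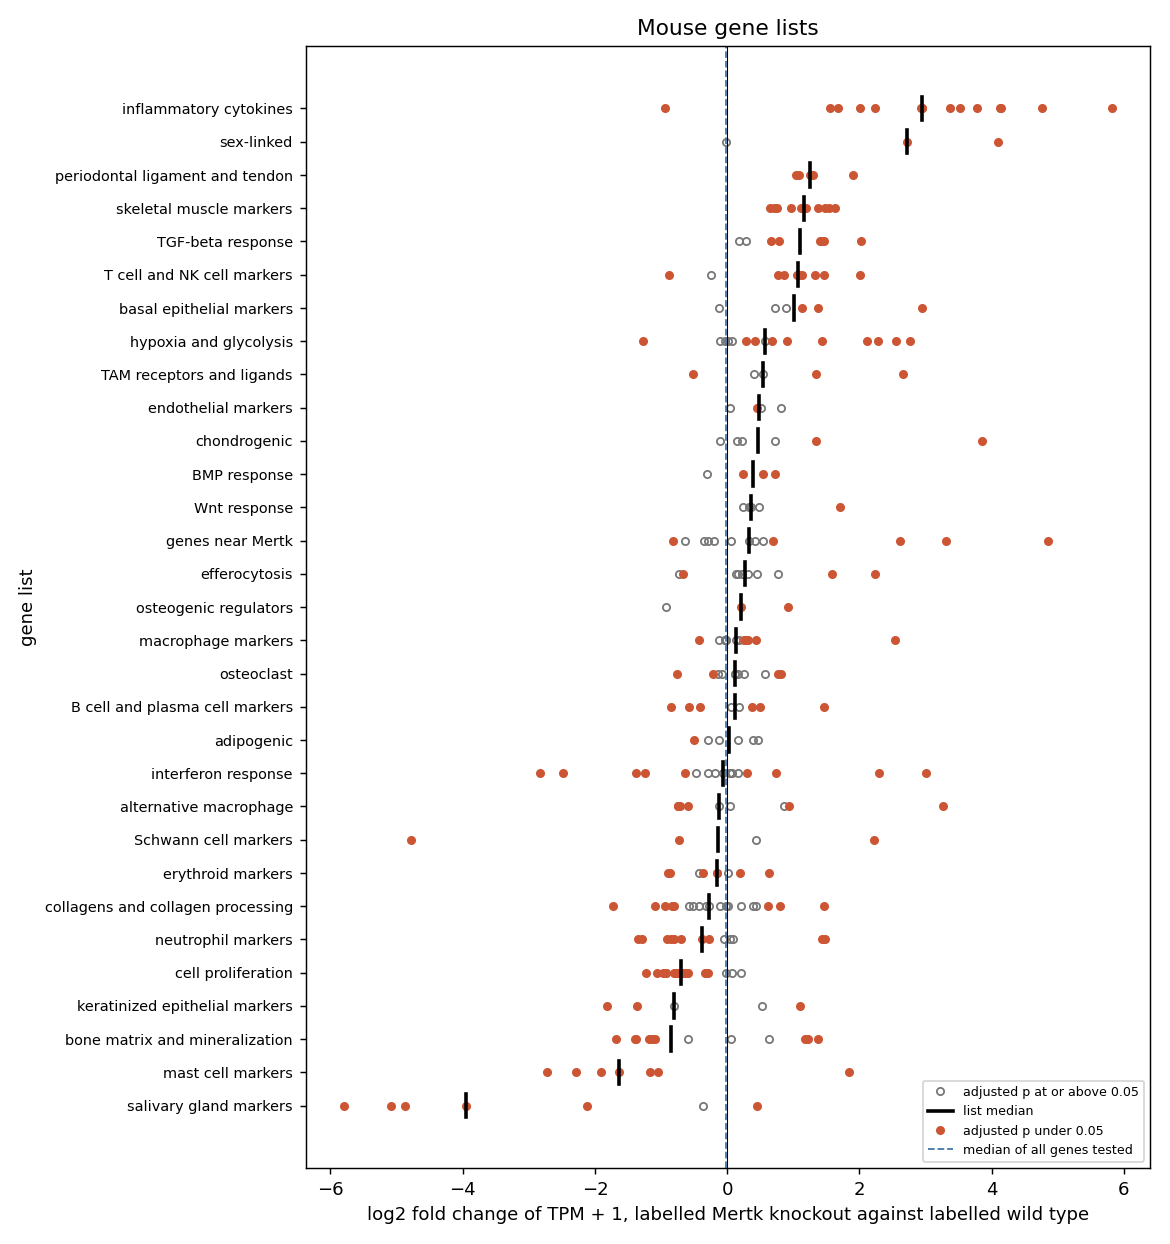
Log2 fold changes of libraries labelled knockout over labelled wild type (horizontal axis) for the members of mouse gene lists (vertical axis); filled orange points passed an adjusted p of 0.05, open grey points did not, black bars are list medians and the dashed blue line is the median of all genes, -0.02. Inflammatory cytokines centre at 2.95 and proliferation genes at -0.69.

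At an unadjusted p under 0.05 there were 6007 mouse genes, and groups did not overlap in 6443 (48.6%, against 10% by chance). With median-ratio scaling, which moved the median log2 fold change of all genes from -0.02 to 0.09, 2819 genes rose and 1625 fell, and all 2325 rises and 1625 of the 2480 falls were kept. Mertk and the Y-linked genes Ddx3y, Eif2s3y and Uty, higher in the libraries labelled knockout, divided the libraries as the labels did. Kdm5d did not, nor did Xist, at 2.69, 0.53 and 1.26 TPM labelled wild type and 1.19, 1.53 and 1.23 TPM labelled knockout. Differences of genotype, of sex and of anything else that went with the labels, such as genetic background, could therefore not be separated. Calls of named genes that rested on single libraries were those of Pros1 (adjusted p of 0.061 to 0.18 without any 1 library other than knockout replicate 1), Atf4 (0.0503 to 0.12, other than knockout replicate 3) and Runx2 (0.057 without wild-type and 0.068 without knockout replicate 3). Runx2 also lost its call with no filter (0.066) and quantile normalization (0.056), and Atf4 without the trend (0.13) and with the replicate block (0.060). Pros1 lost its call with no filter (0.097), without mitochondrial, ribosomal protein and haemoglobin genes (0.056), without the trend (0.0504) and with the block (0.086). By contrast, Gas6 rose without the trend (0.036), Sp7 fell without knockout replicate 2 (0.017) and with quantile normalization (0.024), and Krt14 rose without wild-type replicate 3 (0.047).

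The last comparison asks whether human genes that changed with RXDX-106 moved in the mouse libraries labelled Mertk knockout. Of 130 named human genes that rose, 95 were tested in mouse under the same symbol, where 20 rose and 14 fell, with a median log2 fold change of 0.12 and a limma camera adjusted p of 0.33. Of 7 named human genes that fell, 4 were tested in mouse, and 3 of these rose. They were Tnfaip2 (log2 fold change 1.80), mt-Nd4l (1.72) and Tmem158 (0.86), while Crabp2 (-0.05) did not pass. That list moved up, opposite to the human cells, with limma camera adjusted p = 0.012, and adjusted p = 0.16 with an estimated correlation. Without mt-Nd4l the adjusted p was 0.086. Mitochondrially encoded transcripts took 0.829% ± 0.0916 of TPM in the libraries labelled wild type and 1.88% ± 0.129 in those labelled knockout, and 2.18% ± 0.245 in untreated and 1.65% ± 0.0639 in treated human cells. Among the 100 human genes with the smallest p in each direction, the mouse counterparts of those lower in treated cells also lay higher: 45 matched, 19 rose and 4 fell. The 100 lower genes include the 7 already tested. Only 10 human genes fell past the threshold, so most of these 100 did not pass in human cells. Neither an estimated correlation nor leaving out mitochondrially encoded genes was tried on them. Of those higher in treated cells 75 matched, 17 rose and 11 fell. Unadjusted limma camera p-values at the preset correlation were 7.7e-05 and 0.38 for the lower and the higher genes. The direction of each mouse change follows the labels as given, which Mertk opposes.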

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

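Rescaling without structural RNAs, median-ratio scaling combined with an estimated correlation, and leaving mitochondrially encoded genes out of the human genes matched to mouse were chosen after the data were seen, and the other settings beforehand. In mouse, 3712 to 5046 genes passed under the fits tried, Mertk stayed higher in the libraries labelled knockout in each fit that tested it (a minimum mean of 5 TPM left it out), and of all comparisons of a list with its deposited-scale result 472 kept direction and side of the threshold, 7 weakened, 2 strengthened and 5 reversed. For named mouse genes these numbers were 1171, 21, 4 and 6. Human results moved more: for lists 244, 42, 8 and 10, and for named genes 688, 189, 103 and 9. For each change below the cause was not tested, though fewer libraries or other genes enter some fits. Depth is unknown from TPM, so its part in the calls of scarce genes cannot be stated.

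Human genes changed by RXDX-106 (147) numbered 0 with no filter (limma, 4390 at an unadjusted p under 0.05, 29477 genes tested), 952 with a mean of at least 5 TPM, 387 with median-ratio scaling, 331 with quantile normalization, 0 without the trend (limma, 3583 unadjusted), 6014 with array weights, 376 without structural RNAs and 2 to 3096 on leave-one-out. Human lists past the threshold (9) numbered 5 with a mean of at least 5 TPM, 4 with array weights, 0 with an estimated correlation, 2 with this and median-ratio scaling and 5 to 8 on leave-one-out. Mouse lists (12) numbered 1 with an estimated correlation, 2 with this and median-ratio scaling and 28 with fry, which asks a different question. The mouse test of human genes that fell had p = 0.078 (adjusted p = 0.16) with limma camera at an estimated correlation and p = 0.043 without mitochondrially encoded genes (adjusted p = 0.086).

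With the replicate number as a block, 0 human genes passed (limma, 3717 unadjusted) and 4424 mouse genes did. The labels do not say that equal numbers pair libraries, and this pairing leaves fewer residual degrees of freedom.

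Values that changed direction, none past the threshold, were as follows. Human gene GAS6 had log2 fold changes of -0.19 with median-ratio scaling, -0.10 with quantile normalization, -0.12 without structural RNAs and -0.0195 to 0.115 on leave-one-out. Human gene RUNX2 had -0.0267 and -0.0417 with the first 2 of these, human gene ADM -0.0174 with median-ratio scaling, and human gene TYRO3 -0.224 to 0.0167 on leave-one-out. Mouse gene Xist had 0.0755 with a pseudocount of 0.1, 0.0537 with median-ratio scaling, 0.11 with array weights and -0.32 to 0.31 on leave-one-out. Camera adjusted p-values of lists were 0.351 for human collagens with median-ratio scaling. Stromal cell markers had 0.446 with no filter, 0.968 with array weights and 0.506 to 0.810 on leave-one-out. Matrix proteases had 0.383 with no filter, 0.529 with quantile normalization and 0.742 to 0.905 on leave-one-out. Human osteogenic regulators had 0.948 with array weights and 0.513 to 0.981 on leave-one-out. In mouse, osteogenic regulators had 0.740 with no filter, B cell and plasma cell markers 0.888 to 0.950 and adipogenic genes 0.710 to 0.979 on leave-one-out.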

Other observations

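The tests of macrophage RNA, of exchanged labels, of a shared RNA source and of nasal tissue were chosen after the result was seen, as were the lists of nasal genes; the structural RNA test and the counts over other splits were set down before, the former once the counts with median-ratio scaling were known. Genes named in this paragraph and the next were picked after their values were seen. The cytokine genes Il17a (2.06 to 47.2 TPM, adjusted p = 1.0e-06), Il17f (3.27 to 131 TPM, adjusted p = 2.8e-10) and Il22 (0.0633 to 21.8 TPM, adjusted p = 1.2e-07) were higher in the libraries labelled knockout. Fth1, the heavy chain of the iron store ferritin, rose (5325 to 20435 TPM, adjusted p = 1.0e-12), while the gene Gm6619 fell (20491 to 7846 TPM, adjusted p = 6.0e-11). Whether Fth1 and Gm6619 share reads was not tested, so both changes are uncertain. Antibody variable genes went both ways, with 25 of 77 tested higher and 43 lower in the libraries labelled knockout.

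Of 12 tested genes for odorant carriers of nasal glands, 3 rose and 9 fell, with a median log2 fold change of -1.85, and Obp1b (14228 to 3342 TPM, adjusted p = 2.6e-11) and Obp2a (11925 to 3114 TPM, adjusted p = 2.4e-12) were among the falls and Bpifb9b (8353 to 25805 TPM, adjusted p = 2.1e-11) among the rises. Of 25 tested olfactory and airway epithelial genes, 21 rose and 1 fell, with a median of 2.28. They included Omp, a marker of olfactory neurons (2.04 to 26.4 TPM, adjusted p = 1.9e-06).

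Mertk was higher in the libraries labelled knockout, by a log2 fold change of 2.65. More macrophage RNA in those libraries would raise macrophage markers about as much, but the upper quartile of their log2 fold changes was 0.27, below the lower limit of 2.04 for Mertk. Of the 13 markers tested 5 rose and 1 fell. The test covers the markers as a set, so a rise of a subset of macrophages, for which they need not stand, stays open and untested. Exchanged group labels stay open: the libraries labelled wild type held 0.43 TPM of Mertk, about as little as a knockout might leave. The allele is not given in the sources used here, and TPM do not show which part of the gene the reads came from, so a deleted or extended transcript that still yields reads remains possible. A biological change of Mertk with genotype or sex was not tested apart from the labels.

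Many mouse genes differed between groups while libraries within a group differed little. Above 300 TPM the median coefficient of variation was 3.48% in the libraries labelled wild type and 3.68% in those labelled knockout. If the 3 libraries of a group came from 1 shared RNA source, antibody variable genes, which differ between animals, should vary no more than other genes of their level. Their median coefficient of variation was 17.7% against 8.96% for matched genes in the libraries labelled wild type, a ratio of 1.98, and 17.6% against 11.3% in those labelled knockout, a ratio of 1.56. These values lay beyond the bound set for this test. Yet short histone genes, a control chosen after the result was seen, also exceeded matched genes, with ratios of 1.16 and 1.27. Short genes may therefore vary more for technical reasons. The test also held no value for the spread between separate animals, so the source cannot be told apart. Different amounts of one and the same nasal tissue would move both nasal lists one way, but over genes whose values had not been seen when the lists were drawn up, 5 of 7 odorant carriers fell and 2 rose, while 14 of 18 olfactory and airway genes rose and 1 fell. Their medians lay 3.47 apart, each list past an unadjusted p of 0.05 with fry in opposite directions. Against other genes, limma camera with an estimated correlation had p = 0.0089 for the olfactory and airway list and p = 0.057 for the odorant carriers. The fall of the carriers is thus less sure, and any that share reads with near-identical copies could move apart for that reason. The values speak against 1 tissue in different amounts only if the fall of the carriers holds. Separate tissues at the socket's edge stay open and untested.

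More human genes rose than fell, 93.2% of those called, while structural RNA took a lower mean share of TPM in treated libraries, although untreated replicate 2, at 35.5%, lay within the treated range of 33.8% to 36.1%. If that share alone lowered other transcripts in untreated libraries, its removal should bring the share that rose under 60%, and if it had no part, the share should stay at or above 85%. It was 63.3%, between both bounds, so a lower share of structural RNA is a candidate explanation for part of the excess and cannot be told apart from an effect of treatment. With median-ratio scaling 40.3% of called genes rose, and with quantile normalization 55.3%. The excess thus holds for the TPM as deposited and not after scaling between libraries. Such scaling takes out a shift of most genes whatever its cause. The 2 RNAs RN7SL1 and RN7SL2 took 28.3% ± 3.32 of TPM untreated and 18.6% ± 0.807 treated (n = 3).

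With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For human genes, human lists, mouse genes and mouse lists, 1 of the 10 splits, the real one, gave as large a count. The real counts were 147, 9, 4805 and 12, and the highest of the other splits were 5, 3, 2 and 5. Every other split mixes the real groups, so any real difference adds to the spread within its groups and lowers its gene count. These counts therefore do not show what libraries without a difference would give. For the human genes that rose, tested in mouse, 5 of 10 splits gave as small a limma camera p-value. It was 0.33 for the real split, and the smallest of the others was 0.025.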
